A study of Mus musculus with 8 samples.

How the data were processed

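The series holds 8 single-cell RNA libraries made with a 10x 3' kit from embryonic mouse back skin, per the labels, which also say that the skin was dissected and digested with collagenase and trypsin. The mice were wild-type (WT), heterozygous (HET) or knockout (KO) for Trp63, which encodes the transcription factor p63, with a GFP knock-in at the deltaN form named for the mutant allele. They were taken at embryonic day 13 (E13) or 15 (E15). Each age had 1 WT library, 1 HET library and 2 KO libraries. The series design names a control arm and a p63 KO arm, so WT and HET libraries were joined as control (n = 4) and compared with KO (n = 4). The deposited values were counts, as whole-number UMI (unique molecular identifier) counts per gene and barcode without normalisation. Cell Ranger, Seurat and the mm10 genome were named per the submitters' processing notes, with no versions, and any filter the authors put on barcodes was not stated.

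The gene table had 27998 genes, and 121 gene IDs shared a symbol with another ID and were kept apart by ID. Coordinates came from GENCODE M21 on GRCm38 (mm10), and 330 of 330 named gene IDs matched it. Depth ranged from 8177867 to 26456164 UMIs per library. Female and male libraries were told apart from Xist and Y-linked genes. All E13 libraries had Xist at 1141 to 1537 CPM (UMIs scaled per library total), and all E15 libraries had Y-linked genes at 126 to 151 CPM, so age could not be separated from sex. KO and control libraries had the same sex within each age.

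Barcodes with at least 1000 genes and at most 10% mitochondrial UMIs were kept. Doublets were removed by a score computed per library against 2 simulated doublets per cell, from 1000 genes and 20 components, at 0.8% per 1000 cells. Of 8339 barcodes, 853 failed the filter and 60 were removed as doublets, which left 7426 cells (89.1%). Of the 853 barcodes that failed, 691 had mostly haemoglobin UMIs, so the share of red cells depended on the filter. The filter also removed epithelial-like cells of E15 control libraries, since the looser filter gave 79 in E15 WT and 55 in E15 HET (56 and 26 with the filter used) and 17 and 51 in the E15 KO libraries (16 and 49).

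Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 1) gave 32 clusters without batch integration. Genes of the epithelial response lists, cell-cycle, mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out of the variable genes. A cluster was named after 1 of 14 cell types when at least 3 of that type's markers were each detected in at least 20% of its cells and at 0.25 or more of their level in the highest cluster. A cluster stayed unnamed when its 10 leading genes held more markers of another type than of its own, or when its cells were shallow with no marker leading. Cluster 27 had 10 fibroblast markers and stayed unnamed because the neuron marker Stmn2 was among its leading genes and no fibroblast marker was. The types were epithelial, fibroblast, endothelial, mural, macrophage, mast, lymphoid, melanoblast, Schwann, muscle, erythroid, neuron, cartilage and Merkel. The epithelial markers were Epcam, Cdh1, Cldn6, Cldn7, Esrp1, Esrp2, Grhl2, Rab25, Ap1m2, Spint1, Lsr and Prss8, a set without Trp63 and without keratins, though Epcam and Cldn6 are also reported as results.

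This naming rule replaced a first rule based on a marker z-score. The first rule left 3126 of the 7426 cells without a name, named 2300 cells fibroblast-like and 637 epithelial-like, and gave no fibroblast-like cell at E13. It was replaced after the cluster table was seen and before any KO against control test was run, and the first rule was kept as an alternative. Cluster names are called "-like" classes here because they rest on RNA markers alone.

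UMIs of a class were summed per library into pseudobulk profiles. A library with fewer than 10 cells of a class was left out of that class. The epithelial-like and fibroblast-like classes had at least 10 cells in all 8 libraries, no other class did, and KO against control was therefore not run in other classes. Genes passed filterByExpr at a minimum count of 10. Libraries were scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3, and p was adjusted by the Benjamini-Hochberg method, with 0.05 as the limit. KO against control was fitted as age plus arm with 5 residual degrees of freedom. The effects at each age, their difference and the age effects within each arm came from 1 mean per age and arm with 4 residual degrees of freedom. HET against WT came from age plus genotype, also with 4. The p-values measure the spread between these libraries alone. The SE given with a log2 fold change of edgeR was its absolute value divided by the square root of its F statistic. It was therefore derived from the test and is not a standard error estimated in the fit. For genes with few counts in 1 arm it may not measure how well the fold change is known.

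A total of 35 gene lists, 7 of them markers of other cell types, were fixed before the data were examined, as were the groups, tests and filters. The epithelial response lists were basal keratinocyte, p63 target, basement membrane and hemidesmosome, differentiation, desmosome and junction, simple epithelium, periderm and hair placode. The signalling lists were Wnt response, Hedgehog response, Notch pathway, BMP and TGF-beta response, and FGF and ERK response. The tissue lists were mesenchymal genes, fibrillar matrix, upper dermis, dermal condensate, lower dermis and fat, bone and cartilage, anterior Hox and posterior Hox. The state lists were S phase, G2 and M phase, interferon response, p53 response, hypoxia and glycolysis, dissociation stress, and MHC class I and antigen presentation. The lists for other cell types were fibroblast, endothelial, macrophage, muscle, erythroid, neuron and cartilage markers, with epithelial markers in place of fibroblast markers inside the fibroblast-like class. Some lists shared genes, so their results are not independent. The upper dermis and Wnt response lists shared Lef1, Axin2, Apcdd1 and Dkk1, and Lef1 was also in hair placode. The p63 target list shared Jag2, Bnc1 and Trim29 with basal keratinocyte and Itga3, Dst and Fras1 with basement membrane and hemidesmosome.

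Lists were tested with limma 3.58.1 camera, which compares list members with the other genes, at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes. The preset correlation calls lists easily, since 13 lists were called in epithelial-like cells and 11 in fibroblast-like cells for HET against WT, where no gene was called. Adjustment was over all lists of a comparison for lists, over all tested genes for genes, and, where stated, over the list alone.

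Shares of cells were compared by an exact permutation test over the 70 ways of assigning 4 of 8 libraries to KO, whose smallest possible p was 0.0286, adjusted over 11 classes. Detection shares, the percentage of epithelial-like cells with at least 1 UMI of a gene, were compared the same way for 9 genes after thinning each cell to 2000 UMIs. A count of 0 was read as at most 3 counts, and intervals are 95% Poisson or Wilson intervals. Intervals and floors cover counting error only.

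Genes were named in the report by rule. Trp63 and the 9 detection genes were named. For each comparison the 6 largest rises and 6 largest falls were named among genes with adjusted p below 0.05, at least 50 CPM in the higher arm, and both libraries of 1 arm on the same side of both libraries of the other at each age. In comparisons of ages the same was asked of the 2 later against the 2 earlier libraries. Predicted genes, clone names, mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix and Y-linked genes were left out of this step. Up to 3 called members with the smallest p were named per list, or the 1 with the smallest p if none was called. Not every gene named by the rule is printed in the report. Results of 2 genes that the rule named are not reported here and are left out of the gene counts under alternatives, and 1 of them changed direction under an alternative.

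The fits were tested on simulated data. With 200 changed genes in the epithelial-like fit, 74.5% of 2-fold and 99.0% of 4-fold changes were recovered, and 21 of 191 calls were false. In the fibroblast-like fit 81.0% and 98.9% were recovered, and 11 of 185 calls were false. With no gene changed, 1 gene and 3 genes were called. At E13 alone, 60.6% of 2-fold and 98% of 4-fold changes were recovered in epithelial-like cells, and 23 of 181 calls were false. At E15 alone, 23.2% and 62% were recovered, and 7 of 92 calls were false. Of 200 random lists, camera gave p below 0.05 in 0.5% and 0%. The genes were simulated independently of each other, so this does not show how often camera calls lists of correlated genes.

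Alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no gene filter, thinning of libraries or cells, looser (500 genes, 20% mitochondrial) and stricter (1500 genes, 5%) filters, no or 2 times the doublet removal, Leiden resolutions 0.5 and 2, response genes kept in clustering, and a per-cell gate on 2 markers. Further ones were WT or HET alone as control, the average of the 2 age effects, a replicate block, red cells left out of the denominator, assignments within age, and each library left out in turn. Alternatives chosen after the data were seen were the first naming rule, unnamed clusters added to the fibroblast-like class, libraries with fewer than 30 epithelial-like cells left out, and libraries with over 10 CPM of Hoxa10 left out. Clustering used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, sklearn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2, and plots used matplotlib 3.10.9. No file of the series was left unused.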

Results

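Single-cell RNA libraries were made from the dissected back skin of mouse embryos at E13 and E15 that were WT, HET or KO for Trp63, the gene of the transcription factor p63. Each age had 1 WT, 1 HET and 2 KO libraries, and WT and HET libraries together formed the control (n = 4 against n = 4 KO). In the order E13 WT, E13 HET, E13 KO 1, E13 KO 2, E15 WT, E15 HET, E15 KO 1 and E15 KO 2 the libraries held 22422659, 26456164, 24887466, 17191558, 8177867, 14875484, 16813082 and 21551811 UMIs. They kept 897, 1183, 1076, 707, 503, 769, 975 and 1316 cells with median depths of 18302, 16353, 17943, 18752, 13767, 14187, 13760 and 13458 UMIs. Of all kept cells, 686 (9.2%) were epithelial-like and 5171 (69.6%) fibroblast-like. The epithelial-like class had 177, 160, 91, 111, 56, 26, 16 and 49 cells per library, and the fibroblast-like class had 585, 783, 723, 488, 333, 561, 760 and 938. No 2 libraries had the same profile.

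The first question was how far the targeted gene itself was reduced. Trp63 (ENSMUSG00000022510, GRCm38 chromosome 16, 25683763 to 25892102, plus strand) had 959 and 563 UMIs in epithelial-like cells of the E13 WT and HET libraries, which were 143 and 90.4 CPM. In the 2 E13 KO libraries Trp63 had 19 and 20 UMIs, or 4.25 and 4.23 CPM. At E15 Trp63 had 181 and 64 UMIs in the WT and HET libraries, or 209 and 118 CPM. The E15 KO libraries had 0 UMIs of Trp63, which allows up to 4.48 CPM, and 2 UMIs, or 1.31 CPM (Poisson interval 0.159 to 4.73). In edgeR the log2 fold change of Trp63 between KO and control was -5.34 ± 0.40 (SE, n = 4 against 4, adjusted p = 2.62e-05). The 3' tag may lie outside the changed part of the gene, and it counts the TA isoforms as well as the deltaN isoforms.

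The next comparison asked whether the cell types of the skin differed in abundance between KO and control. Melanoblast-like cells, the pigment cell precursors, made up 0.369% ± 0.341 (SD, n = 4) of KO cells and 1.31% ± 0.363 of control cells (exact permutation p = 0.0286, adjusted p = 0.314). Schwann-like glia were 1.05% ± 0.334 in KO and 2.53% ± 1.28 in control (exact permutation p = 0.0571, adjusted p = 0.314). These SDs and the test join both ages. At E13 the KO libraries were at 1.49 and 1.13% and the control libraries at 3.34 and 3.89%, and at E15 at 0.821 and 0.76% against 1.59 and 1.3%. Epithelial-like cells were 19.7, 13.5, 8.46, 15.7, 11.1, 3.38, 1.64 and 3.72% of the 8 libraries in the order given, with means of 7.38% ± 6.24 in KO and 11.9% ± 6.76 in control (exact permutation p = 0.371). With a looser cell filter the E15 HET library had 55 epithelial-like cells in place of 26, and E15 WT 79 in place of 56. Fibroblast-like cells were 71.4% ± 4.70 of KO and 67.6% ± 3.57 of control cells (exact permutation p = 0.257). No class passed adjustment over the 11 classes. A single class could not pass, since the smallest possible p of 0.0286 became 0.314 after adjustment, so these tests do not show that abundance was unchanged.

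The other classes did not pass either. Endothelial-like cells were 2.20% against 1.41% (exact permutation p = 0.2), muscle-like cells 3.998% against 2.30% (p = 0.171) and mural-like cells 2.75% against 2.05% (p = 0.6). Macrophage-like cells were 1.87% against 1.75% (exact permutation p = 0.886) and erythroid-like cells 2.99% against 2.68% (p = 0.886). The means over both ages hide opposite differences in some classes, which were not tested by age. Erythroid-like cells were 1.59% of KO and 4.75% of control cells at E13 and 4.39% and 0.62% at E15, endothelial-like cells 3.04% and 1.245% and then 1.36% and 1.58%, and mural-like cells 1.05% and 1.35% and then 4.45% and 2.75%. Mast-like cells, whose cluster also carried the neutrophil genes S100a8 and Ngp, were 3.15% against 2.997% (exact permutation p = 0.943). They were 0 of 897 cells in the E13 WT library, which allows a share of up to 0.334%, and 3.78 to 7.28% of the E15 libraries. Unnamed cells were 2.88% of KO and 3.39% of control cells (exact permutation p = 0.971), or 0.334, 0.085, 9.85, 0.99, 7.16, 5.98, 0.513 and 0.152% of the libraries. Of the 110 cells in unnamed cluster 26, led by the cartilage-associated genes Mgp and Col2a1, 104 came from E13 KO 1. Unnamed cluster 27, led by Ebf1, Stmn2, Bmp4, Bmp3 and Ptch1, had 33 and 39 cells in the E15 WT and HET libraries and 0 in KO.

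**Figure D1:**
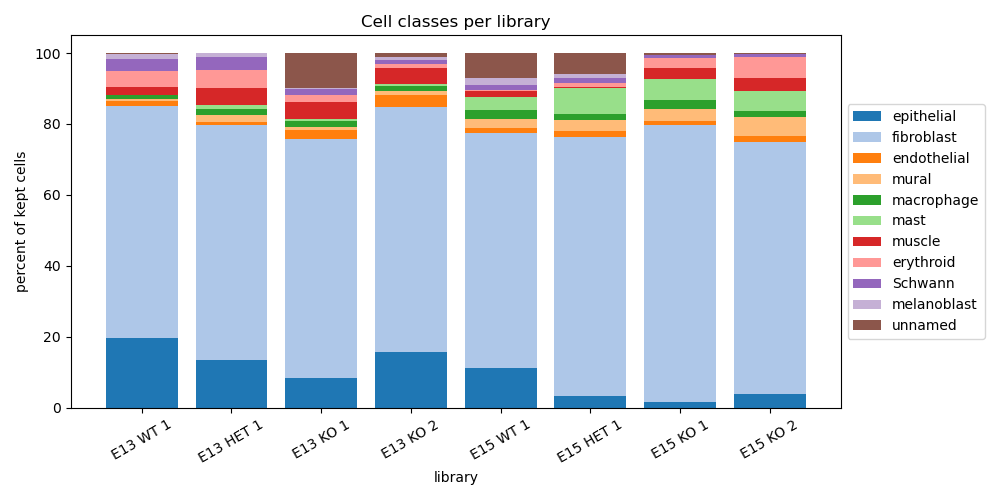
Percent of kept cells (vertical axis) in each of 11 cell classes, 1 stacked bar per library, with colours for the classes. Fibroblast-like cells were the largest class in each library, and epithelial-like cells ranged from 1.64% to 19.7%.

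Cluster membership of epithelial-like cells differed between the arms. Cluster 9, led by Gjb2, Krt14 and Krt5, held 161 and 146 cells of the E13 WT and HET libraries. Cluster 15, led by Krt18, Krt8 and Epcam, held the 91 and 111 E13 KO cells and 6 control cells. At E15 the 16 and 49 KO cells were in cluster 28, led by Krtdap, Dmkn and Krt15. Control cells at E15 were in cluster 31, led by Krt17, Krt5 and Krt14, and in cluster 29, led by the differentiation genes Krt1, Krt10 and Lor. Epithelial-like cells had median depths of 26938, 25339, 44315, 37590, 14178.5, 16216, 30617.5 and 21142 UMIs in the 8 libraries, so depth was higher in KO than in control at each age.

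The share of epithelial-like cells with a UMI of each marker was therefore compared after thinning to 2000 UMIs. Trp63 was detected in 1.01% ± 0.837 (SD, n = 4) of KO and 19.2% ± 9.60 of control cells, and Krt5, a basal layer keratin, in 7.20% ± 7.19 and 64.5% ± 12. Krt14, the partner of Krt5, was detected in 1.02% ± 2.04 of KO and 79.8% ± 12.6 of control cells. Krt8, a keratin of simple epithelia, was detected in 70.7% ± 11.8 of KO and 1.45% ± 1.49 of control cells, and its partner Krt18 in 61.1% ± 26.7 and 1.35% ± 1.06. Epcam, an epithelial adhesion gene that was also a naming marker, was detected in 74.5% ± 4.51 and 39.3% ± 9.65. Each of these 6 genes had an exact permutation p of 0.0286 and an adjusted p of 0.0429.

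The remaining detection genes did not pass. Krt1, a suprabasal keratin, was detected in 1.81% of KO and 27.3% ± 25.5 of control cells (exact permutation p = 0.0571, adjusted p = 0.0735). Krt15 was detected in 48.2% ± 42.0 of KO and 64.5% ± 11.1 of control cells (exact permutation p = 0.486), which joins 11.9% against 67.9% at E13 and 84.5% against 61.0% at E15, and Krt10 in 16.9% and 29.1% (exact permutation p = 0.4). As a measure of free RNA, thinned fibroblast-like cells (median depth 14900 UMIs before thinning, against 27045 in epithelial-like cells) had Krt14 in 10.1 to 21.6% of cells per control library and 0 to 0.53% per KO library, and Krt5 in 2.17 to 8.02% and 0.13 to 0.53%. Krt8 was in 0 to 0.51% of control and 0.92 to 8.81% of KO fibroblast-like cells, Krt18 in 0 to 0.34% and 0.53 to 10.25%, Epcam in 0.3 to 1.66% and 0.75 to 8.81%, and Trp63 in 0.38 to 1.5% and 0%. Among the 130 endothelial-like cells (median 34469.5 UMIs), Krt14 was in 7.14 to 37.5% per control and 0% per KO library, Krt5 in 0 to 7.14% and 0%, and Trp63 in 0% of both. Krt8, Krt18 and Epcam were in 0% of endothelial-like cells in control libraries and in 0 to 9.09, 0 to 16.67 and 0 to 4.76% in KO libraries. In fibroblast-like cells Krt1 was in 2.22 to 11.71% per control and 0.32 to 1.66% per KO library, Krt10 in 5.3 to 24.02% and 3.89 to 7.75%, and Krt15 in 5.36 to 12.61% and 0.83 to 6.5%.

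The main question was what the epithelium expressed without p63. In epithelial-like cells of clusters 9, 15, 28, 29 and 31, KO and control differed by edgeR in 2383 of 10996 genes, of which 1233 rose and 1150 fell. Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548) changed by log2 -7.04 ± 0.81 (SE, n = 4 against 4, edgeR adjusted p = 0.000331), from 1431 to 3.13 CPM at E13 and from 2089 to 42.3 CPM at E15. Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) changed by -5.03 ± 0.65 (edgeR adjusted p = 0.000614), from 565 to 6.35 CPM at E13 and from 1298 to 97.7 CPM at E15. Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027) rose by 6.41 ± 0.39 (edgeR adjusted p = 8.3e-06), from 10.6 to 1134 CPM at E13 and from 5.77 to 357 CPM at E15. Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482) rose by 5.69 ± 0.56 (edgeR adjusted p = 0.000144), from 12.5 to 854 CPM at E13 and from 14.2 to 598 CPM at E15. Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129) rose by 1.23 ± 0.17 (edgeR adjusted p = 0.000843). Krt1 changed by -5.35 ± 1.01 (edgeR adjusted p = 0.00471), whereas Krt10 at -3.30 ± 1.08 (edgeR adjusted p = 0.0526) and Krt15 at -1.41 ± 0.93 (edgeR adjusted p = 0.31) did not pass. Krt5 and Krt14 were lower and Krt8 and Krt18 higher in 4 of 4 KO libraries than in any control library. The count of 2383 was 1484, 1549, 1451 and 1448 when E13 WT, E13 HET, E13 KO 1 or E13 KO 2 was left out, and 246 of 2453 tested genes when each cell was thinned to 2000 UMIs.

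**Figure D2:**
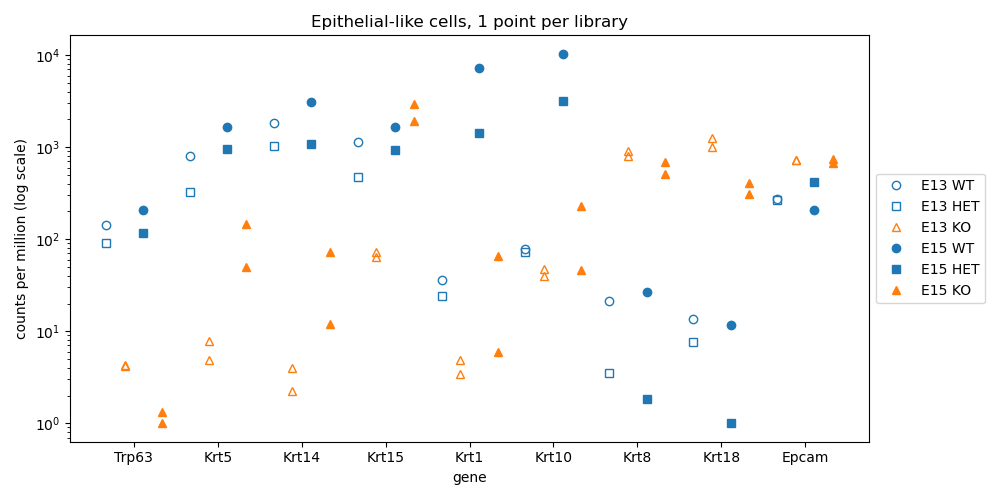
CPM on a log scale (vertical axis) of 9 genes in epithelial-like cells, with 1 point per library, blue for control and orange for KO, open for E13 and filled for E15, and values under 1 drawn at 1. Krt5 and Krt14 were lower and Krt8 and Krt18 higher in KO than in control at both ages, while Krt15 was lower in KO at E13 alone.

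The largest changes lay in genes of several kinds. Fst, which encodes the activin antagonist follistatin, changed by log2 -7.19 ± 0.52 (edgeR adjusted p = 2.17e-05), the surface antigen gene Ly6d by -7.17 (0.000794), and the lipid transfer gene Pltp by -6.18 ± 0.27 (1.82e-06). Col17a1, which encodes a hemidesmosome collagen, had 2 UMIs in KO, and its control to KO ratio was 151 (Poisson interval 41.5 to 1.25e+03). Among the rises, Slc40a1, the iron exporter ferroportin, gained 5.17 ± 0.34 (edgeR adjusted p = 1.43e-05), the intermediate filament gene Bfsp2 5.42 ± 0.54 (0.000146) and the uroplakin-like gene Upk3bl 4.52 ± 0.44 (0.000127). The carboxypeptidase gene Cpa4 had 1 UMI in control and a KO to control ratio of 439 (Poisson interval 78.3 to 1.74e+04). Ifitm3, an interferon-inducible membrane gene, changed by -3.45 ± 0.13 (edgeR adjusted p = 9.72e-07).

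Genes of the basal layer and its attachment fell as groups. In the basal keratinocyte list 10 of 13 tested genes fell, among them Bnc1 (-5.33 ± 0.44, edgeR adjusted p = 4.9e-05) and Fermt1, the kindlin gene of focal adhesions (-2.79 ± 0.21, 2.99e-05). The median of this list was -2.79 (camera adjusted p = 3.41e-10, adjusted p = 0.0552 with an estimated correlation). In the p63 target list 9 of 20 genes fell and 1 rose (camera adjusted p = 8.42e-06, adjusted p = 0.145 with an estimated correlation), with Dst at -2.50 ± 0.20 and Pvrl1, a nectin gene mutated in clefting with ectodermal dysplasia, at -2.17 ± 0.23. In the basement membrane and hemidesmosome list 8 of 16 genes fell (camera adjusted p = 9.3e-10, adjusted p = 0.0552 with an estimated correlation), including the integrin gene Itgb4 (-1.83 ± 0.20, edgeR adjusted p = 0.000221).

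Epithelial identity lists moved both ways. In the simple epithelium list 7 of 11 genes rose and 1 fell (camera adjusted p = 2.65e-08, adjusted p = 0.0552 with an estimated correlation), and adjusted over the list alone 10 rose. The tight junction gene Cldn3 rose by 4.51 ± 0.51 (edgeR adjusted p = 0.000287). In the differentiation list 6 of 14 genes fell and 1 rose (camera adjusted p = 2.82e-05, adjusted p = 0.388 with an estimated correlation), with the cornified envelope gene Lor at -5.09 ± 0.36 (edgeR adjusted p = 1.93e-05) and Krt77 at -6.09 ± 0.38 (9.79e-06). The desmosome and junction list had 4 rises and 5 falls among 16 genes (camera adjusted p = 0.885), with Dsc3 at -4.44 ± 0.55, Dsp at -1.59 ± 0.20 and the tight junction gene Ocln at 2.14 ± 0.21. The periderm list had 2 rises and 1 fall among 6 genes (camera adjusted p = 0.601). In it Krt17 changed by -3.55 ± 0.55 (edgeR adjusted p = 0.00156) and the GABA receptor gene Gabrp rose by 2.18 ± 0.46 (0.00819).

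Hair placode and Notch genes fell as groups. In the hair placode list 6 of 11 genes fell (camera adjusted p = 1.09e-05, adjusted p = 0.0552 with an estimated correlation), with the Wnt receptor partner Kremen2 at -2.53 ± 0.21, Wnt10b at -2.73 ± 0.40 and the Wnt effector Lef1 at -1.14 ± 0.18 (edgeR adjusted p = 0.00181). The Notch pathway list had 5 falls and 1 rise among 7 genes (camera adjusted p = 6.33e-11, adjusted p = 0.0552 with an estimated correlation). Nrarp, a Notch feedback gene, changed by -2.997 ± 0.14 (edgeR adjusted p = 2.43e-06), Notch1 by -3.001 ± 0.18 (8.3e-06) and the ligand gene Dll1 by -4.01 ± 0.39 (0.000142). In the FGF and ERK response list 4 of 7 genes fell (camera adjusted p = 0.0103, adjusted p = 0.451 with an estimated correlation), namely Spred2 (-1.61), Etv5 (-2.67), Dusp6 (-1.14) and Etv4 (-3.06). The Hedgehog response list had 2 falls among 5 genes (camera adjusted p = 0.0543), with Gli1 at -2.76 ± 0.69 (edgeR adjusted p = 0.0179), and adjusted over the list alone 4 fell. The BMP and TGF-beta response list had 4 rises among 10 genes (camera adjusted p = 0.0756), with Msx2 at 1.55 ± 0.19, Cyr61 at 1.68 ± 0.35 and Smad7 at 1.32 ± 0.36. The Wnt response list had 1 fall among 9 genes (camera adjusted p = 0.343).

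Mesenchymal, dermal and positional lists did not pass in the comparison over both ages. The mesenchymal list had 5 rises and 1 fall among 10 genes (camera adjusted p = 0.246), with Prrx1 at 1.33 ± 0.23 (edgeR adjusted p = 0.0027), Cdh11 at 1.47 ± 0.31 (0.00766) and Snai2 at -2.68 ± 0.26 (0.00012). The fibrillar matrix list had 6 rises and 3 falls among 20 genes (camera adjusted p = 0.207), with Col1a2 at 1.19 ± 0.23, Col3a1 at 1.41 ± 0.28 and Fbln1 at -1.88 ± 0.19. The upper dermis list had 3 falls among 8 genes (camera adjusted p = 0.132), and the lower dermis and fat list had 3 rises and 1 fall among 7 (camera adjusted p = 0.132), with Mfap5 at 2.61 and Cebpa at -1.77. The dermal condensate list had 1 rise among 3 genes (camera adjusted p = 0.907), Enpp2 at 1.28, and its median of -0.24 and mean of 0.21 differed in sign. Anterior Hox genes had 4 falls among 11 (camera adjusted p = 0.132), including Hoxc5 at -1.49 and Hoxa5 at -1.29, and posterior Hox genes had 3 rises among 5 (camera adjusted p = 0.209), namely Hoxd8 at 2.55, Hoxc9 at 1.93 and Hoxb9 at 2.47.

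Proliferation lists fell. In the G2 and M phase list 12 of 24 genes fell (camera adjusted p = 2.17e-06, adjusted p = 0.451 with an estimated correlation), with a median of -0.63 and Top2a, the topoisomerase of dividing cells, at -0.97 (edgeR adjusted p = 0.00731). In the S phase list 9 of 24 genes fell (camera adjusted p = 0.000139, adjusted p = 0.429 with an estimated correlation), including the replication genes Fen1 at -0.85 and Uhrf1 at -1.05. The interferon response list had 2 rises and 1 fall among 5 genes (camera adjusted p = 0.294), Bst2 at 3.38 ± 0.41 (edgeR adjusted p = 0.000471), Ifi27 at 2.52 ± 0.29 (0.000287) and Ifitm3 at -3.45, and its median of -0.16 and the direction of the test were negative while its mean was 0.38. MHC class I and antigen presentation had 4 rises among 6 genes (camera adjusted p = 0.132), including the peptide transporter Tap1 at 1.96 and H2-K1 at 1.44. The p53 response list had 4 falls and 1 rise among 11 genes (camera adjusted p = 0.134), hypoxia and glycolysis 2 falls among 14 (camera adjusted p = 0.132), and dissociation stress 4 rises among 15 (camera adjusted p = 0.132).

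Markers of other cell types were read in the same epithelial-like cells. Fibroblast markers had 6 rises and 2 falls among 12 genes with a median of 1.02 (camera adjusted p = 0.172), with Twist1 at 1.98 and Mfap4 at 1.54. Macrophage markers had 1 rise among 8 (camera adjusted p = 0.207), Pf4 at 1.80 ± 0.57 (edgeR adjusted p = 0.0464), and erythroid markers 1 fall among 7 (camera adjusted p = 0.907), Hbb-y at -0.77, with a median of 0.24 and a mean of -0.06. Neuron markers had 1 rise among 2 (camera adjusted p = 0.988), Stmn2 at 3.64, which also led fibroblast-like clusters 8, 10 and 14 and so did not mark neurons alone. Muscle markers (camera adjusted p = 0.172, 5 genes) and endothelial markers (camera adjusted p = 0.729, 4 genes) had no called gene, and the endothelial median and mean were positive while the direction of the test was negative. Bone and cartilage genes and cartilage markers had too few genes to test here. Fry gave adjusted p from 0.000404 to 0.0264 for the 10 lists that camera called.

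Single-age comparisons asked which of these differences were present at E13, soon after the epidermis is specified. At E13, 1426 genes rose and 1211 fell of 11612 (edgeR, n = 2 against 2). Control cells were in clusters 9 and 29, with 6 in cluster 15, and all KO cells were in cluster 15. The keratins changed by -6.58 (Krt5), -8.91 (Krt14), -3.67 ± 0.41 (Krt15, edgeR adjusted p = 8.7e-05), 6.62 ± 0.37 (Krt18, 9.79e-07) and 5.97 (Krt8). Trp63 changed by -4.87 ± 0.36 (edgeR adjusted p = 4.51e-06) and Krt1 by -2.95 (0.0307), whereas Krt10 was at -0.91 (0.284). Hpgds, a prostaglandin synthase gene, changed by -5.82 ± 0.28 (edgeR adjusted p = 4.17e-07), the basal gene Trim29 by -4.81 (5.19e-07), the p63 target Perp by -4.04 (2.05e-05) and the growth factor receptor gene Fgfr2 by -2.51 (1.32e-05). Col17a1 was at least 54.4-fold lower in KO. Cystm1 rose by 6.78 ± 0.38 (edgeR adjusted p = 8.99e-07), the neuropeptide gene Npy by 4.99 ± 0.39 (2.44e-05), the transcription factor gene Dach2 by 4.42 ± 0.29 (3.29e-06) and Notch3 by 2.58 (4.51e-06). The count of 2637 was 1143, 1283, 1165 and 1045 when E13 WT, E13 HET, E13 KO 1 or E13 KO 2 was left out.

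Camera called 18 lists at E13, and none passed with an estimated correlation. The lowest adjusted p were 1.07e-13 for p63 target (12 of 20 genes fell, adjusted p = 0.0933 with an estimated correlation) and 1.07e-13 for basal keratinocyte genes (12 of 15 fell, adjusted p = 0.114 with an estimated correlation). Simple epithelium genes had 8 rises among 11 (camera adjusted p = 6.6e-09, adjusted p = 0.114 with an estimated correlation). Posterior Hox genes had 6 rises among 7 (camera adjusted p = 5.18e-05, adjusted p = 0.191 with an estimated correlation), with Hoxd9 at 4.67 (edgeR adjusted p = 2.52e-05). E13 KO 2 had 28.5 CPM of Hoxa10 in fibroblast-like cells against 0.282 to 1.46 in the other E13 libraries, so trunk position was not separated from KO for its Hox values. In epithelial-like cells Hoxd9 was at 16.34 CPM in E13 KO 1 and 27.95 in E13 KO 2, against 1.04 and 0.482 in E13 WT and E13 HET. Anterior Hox genes had 4 falls among 11 (camera adjusted p = 0.00129, adjusted p = 0.131 with an estimated correlation), with Hoxa5 at -2.003. Mesenchymal genes had 8 rises and 1 fall among 11 (camera adjusted p = 0.0104, adjusted p = 0.178 with an estimated correlation), fibrillar matrix genes 8 rises and 3 falls among 20 (camera adjusted p = 0.01, adjusted p = 0.175 with an estimated correlation), and other-cell-type fibroblast markers 6 rises and 2 falls among 12 (camera adjusted p = 0.00296, adjusted p = 0.387 with an estimated correlation). Dissociation stress genes had 8 rises and 1 fall among 15 (camera adjusted p = 0.0022, adjusted p = 0.379 with an estimated correlation), with Egr1 at 2.62. Of the neuron marker list, Stmn2 and Nefl rose by 4.16 and 3.33. Stmn2 was also among the leading genes of fibroblast-like clusters 8 and 14, so its rise does not point to neurons.

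At E15, when control epidermis stratifies, 883 genes rose and 966 fell of 11612 (edgeR, n = 2 against 2), with clusters 29 and 31 in control and cluster 28 in KO. Cell quality moved with the arm at E15, where 54 and 68 barcodes were over the mitochondrial limit and 79.5 and 70.7% of barcodes were kept in control, against 6 and 8 barcodes and 86.9 and 87.4% in KO. This difference was not separated from KO in the E15 genes and lists. Krt1 changed by -6.83 ± 0.84 (edgeR adjusted p = 0.000323), Krt10 by -5.63 ± 0.67 (0.000253), Lor by -5.50 (7.5e-07) and Krt14 by -5.55 (0.000245). Krt8 rose by 5.07 and Krt18 by 5.57, while Krt15 was at 0.81 (edgeR adjusted p = 0.162). Genes with 0 UMIs in KO were lower by at least 158-fold for Cnfn, a cornified envelope gene, 98.6-fold for the parathyroid hormone-related gene Pthlh, 59.2-fold for the Wnt receptor gene Fzd10 and 37.9-fold for the hair follicle gene Lhx2. Genes with 0 UMIs in control were higher by at least 118-fold for Cldn3, 94.2-fold for the mucosal keratin Krt4 and 39.4-fold for the arginase gene Arg1. Fgfr2 changed by -5.26, the cadherin gene Cdh3 by -3.79, the laminin gene Lamb3 by -3.41 and the Notch ligand gene Jag1 by -3.75, and Cldn4 rose by 2.86. The Trp63 ratio of control to KO was 191 on 2 KO UMIs (Poisson interval 52.2 to 1.58e+03). The count of 1849 was 1174 without E15 KO 1 and 808 without E15 KO 2.

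Camera called 16 lists at E15, and none passed with an estimated correlation. Differentiation genes had 11 falls and 1 rise among 17 (camera adjusted p = 8.52e-14, adjusted p = 0.223 with an estimated correlation), with a median of -4.28, or -4.14 with members at 0 set to their bound. All 5 tested Hedgehog response genes fell (camera adjusted p = 0.00034, adjusted p = 0.223 with an estimated correlation), including Ptch1 at -3.09 and Gli1 at -3.87. Hair placode genes had 9 falls among 12 (camera adjusted p = 7.03e-10, adjusted p = 0.16 with an estimated correlation), and hypoxia and glycolysis genes 11 falls among 15 (camera adjusted p = 1.49e-07, adjusted p = 0.223 with an estimated correlation), with Ldha at -1.59 and Pgk1 at -2.99. Periderm genes had 2 rises and 1 fall among 6 (camera adjusted p = 0.0198, adjusted p = 0.464 with an estimated correlation), and MHC class I genes 2 rises among 7 (camera adjusted p = 0.0143, adjusted p = 0.29 with an estimated correlation), with Tap1 at 3.43. G2 and M phase genes had 11 falls among 24 (camera adjusted p = 4.67e-08, adjusted p = 0.397 with an estimated correlation). Macrophage markers had 2 rises among 9 (camera adjusted p = 0.0236, adjusted p = 0.609 with an estimated correlation), with Pf4 at 3.54 and Mrc1 at least 5.57-fold higher.

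**Figure D3:**
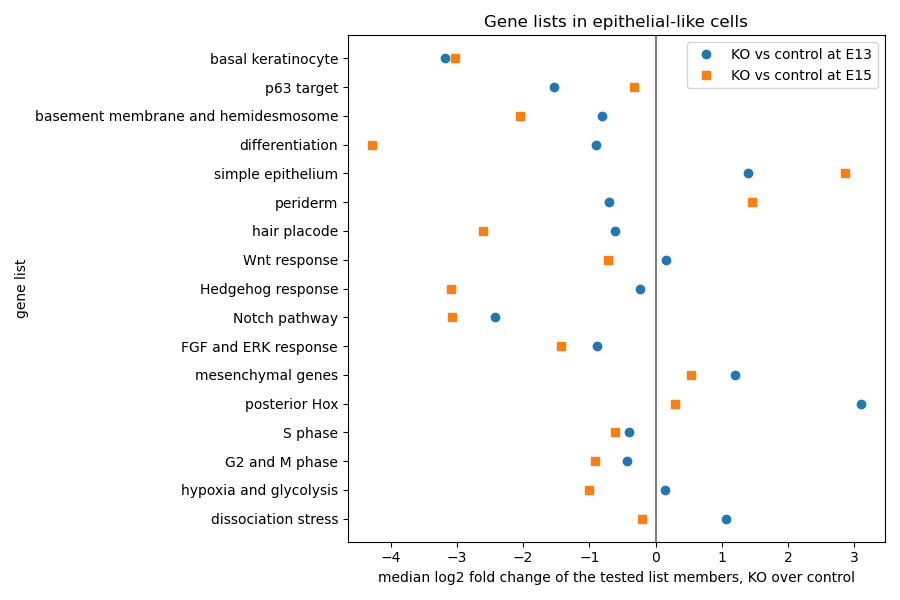
Median log2 fold change of KO over control (horizontal axis) of the tested members of 17 gene lists in epithelial-like cells, with circles for E13 and squares for E15. The differentiation median was -0.91 at E13 and -4.28 at E15, and the periderm median was -0.70 at E13 and 1.46 at E15.

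The interaction of age and KO asked which effects differed between the ages, and 161 genes were higher and 194 lower at E15 by edgeR. The lower cell quality of the E15 control libraries was not separated from the interaction. Krt15 had a difference of 4.48 ± 0.55 (edgeR adjusted p = 0.00276), since it was at 811 CPM in control and 68.4 in KO at E13 and at 1285 and 2413 CPM at E15. The claudin gene Cldn1 differed by 3.37, the secreted keratinocyte genes Krtdap and Dmkn by 3.85 and 4.06, and Krt19 by 6.50 (edgeR adjusted p = 0.0211). Krt10 differed by -4.73 (edgeR adjusted p = 0.0125), the connexin gene Gjb2 by -5.82 (0.000852), Cdh3 by -3.23, Vegfa by -4.36 and Pgk1 by -3.93. Krt5 at 2.83 (edgeR adjusted p = 0.0675), Krt14 at 3.37 (0.084), Krt8 at -0.90 (0.696) and Krt18 at -1.05 (0.538) did not pass. The count of 355 was 1029 without the gene filter, and 180, 108, 76 and 102 when E13 WT, E13 KO 1, E13 KO 2 or E15 KO 2 was left out.

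Changes from E13 to E15 within each arm asked how far the epithelium matured, with age not separable from sex. In control, cell quality was not separated from age either. Barcodes over the mitochondrial limit went from 3 and 7 at E13 to 54 and 68 at E15 in control, and from 7 and 10 to 6 and 8 in KO. In control 1053 genes rose and 733 fell (edgeR, n = 2 against 2). All 17 tested differentiation genes rose (camera adjusted p = 9.88e-60, adjusted p = 0.0715 with an estimated correlation), including Lor by 7.93 (edgeR adjusted p = 1.35e-08), Krt10 by 6.65 (7.38e-05), Krt1 by 7.37 (0.000131) and Krt77 by 9.12. Cnfn was at least 934-fold higher, the glutathione transferase genes Gsta1 and Gsta2 at least 334-fold and 343-fold, and the ceramidase gene Acer1 at least 321-fold. The aquaporin gene Aqp3 rose by 5.06, Ptch1 by 5.21 and the cell-cycle inhibitor gene Cdkn1a by 3.95. Cldn6 changed by -4.24, Gjb2 by -3.20, Hoxc5 by -3.16 and Lef1 by -1.25. S phase genes had 18 falls among 24 (camera adjusted p = 2.21e-12, adjusted p = 0.26 with an estimated correlation), and dissociation stress genes 14 rises among 15 (camera adjusted p = 9.24e-22, adjusted p = 0.0715 with an estimated correlation). The count of 1786 was 972, 954 and 946 without E13 WT, E13 HET or E15 WT.

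In KO 1515 genes rose and 1234 fell from E13 to E15 (edgeR, n = 2 against 2). Dmkn rose by 12.01 (edgeR adjusted p = 1.61e-07), Krtdap by 10.80 (1.21e-07), the kallikrein gene Klk10 by 8.24 and Lor by 5.86. Krt15 rose by 5.30 (edgeR adjusted p = 8.88e-06), Krt5 by 4.19 (0.000462) and Krt14 by 4.08 (0.00342), Krt18 changed by -1.52 (0.00331), and Krt8 was at -0.36 (0.632). The basal and p63 target genes Perp and Trim29 rose by 4.62 and 4.24 and Cldn1 by 5.01. Aox4 was at least 669-fold higher and the serpin gene Serpinb5 at least 195-fold, whereas Npy was at least 62-fold lower. The mast cell marker Cma1 had 1 UMI in E13 KO and an E15 to E13 ratio of 1.05e+03 (Poisson interval 188 to 4.18e+04). Mast-like cells went from 0.608 to 5.70% of KO cells, and whether their RNA reached the epithelial-like profiles was not tested. Differentiation genes had 13 rises among 17 (camera adjusted p = 2.41e-16, adjusted p = 0.232 with an estimated correlation), p63 target genes 11 rises and 3 falls (camera adjusted p = 1.44e-05, adjusted p = 0.232 with an estimated correlation) and periderm genes 5 rises and 1 fall among 6 (camera adjusted p = 6.35e-05, adjusted p = 0.257 with an estimated correlation). S phase genes had 22 falls among 24 (camera adjusted p = 2.76e-15, adjusted p = 0.232 with an estimated correlation), and the macrophage marker Pf4 rose by 3.72. The count of 2749 was 1473, 1532 and 913 without E13 KO 1, E13 KO 2 or E15 KO 2.

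HET against WT asked whether loss of 1 allele changed the epithelium. No gene passed in edgeR with n = 2 against 2 (296 genes had unadjusted p below 0.05), DESeq2 called 3 genes, and 15 passed in edgeR without the gene filter. Krt8 had the smallest p at -2.89 ± 0.37 (edgeR adjusted p = 0.105), and Trp63 was at -0.82 ± 0.34 (edgeR adjusted p = 1). The count of 0 was 2, 1 and 1 without E13 WT, E15 KO 1 or E15 KO 2. Camera called 13 lists here and none with an estimated correlation.

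The comparison in fibroblast-like cells asked how the dermis differed beside a p63-deficient epithelium. The arms filled different fibroblast-like clusters at E15, with 384 KO and 10 control cells in cluster 6, 365 and 33 in cluster 5, 247 and 21 in cluster 11 (led by Clec3b, Mfap5, Dpt and Ly6a) and 51 and 240 in cluster 10. At E13 clusters 2, 4 and 16, with Crabp1 and Twist2 among their leading genes, had 176, 138 and 72 KO cells against 392, 274 and 136 control cells. Clusters 1 and 8 had 378 and 221 KO cells against 298 and 116 control cells. The changes given for the whole class include this mix at each age. Of 12903 genes, 65 rose and 53 fell by edgeR (n = 4 against 4). Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), a Wnt effector of the upper dermis, changed by -1.35 ± 0.22 (edgeR adjusted p = 0.0248), from 64.7 to 37.3 CPM at E13 and from 56.5 to 14.0 CPM at E15. Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598) changed by -1.50 ± 0.23 (edgeR adjusted p = 0.0171) and Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974) by -1.39 ± 0.23 (0.0262), both targets of Hedgehog signalling. The Wnt inhibitor gene Wif1 (ENSMUSG00000020218, chromosome 10, 121033960 to 121100650) changed by -1.09 ± 0.16 (edgeR adjusted p = 0.0169), the anchoring fibril gene Col7a1 by -0.91 ± 0.11 (0.00652), Fgfr2 by -0.63 (0.0228) and Tcf4 by -0.49 ± 0.08 (0.03). With the libraries over 10 CPM of the posterior gene Hoxa10 (E13 KO 2, E15 HET and E15 KO 1) left out, the values were -1.29 for Lef1, -1.504 for Ptch1, -1.56 for Gli1, -0.90 for Wif1 and -0.56 for Tcf4. None of the 5 passed there with 2 residual degrees of freedom (edgeR adjusted p from 0.113 to 0.195), and 18 genes were called. The count of 118 was 51 without E15 KO 2, 36 with WT alone as control and 1093 without the gene filter.

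Rises in fibroblast-like cells included Ptn (ENSMUSG00000029838, chromosome 6, 36714929 to 36810220), a heparin-binding growth factor gene, at 1.64 ± 0.25 (edgeR adjusted p = 0.0171), from 451 to 1040 CPM at E13 and from 203 to 840 CPM at E15. The apolipoprotein gene Apod rose by 1.40 ± 0.21 (edgeR adjusted p = 0.0171), Plagl1 by 1.12 ± 0.19 (0.0262), Klf4 by 1.10 ± 0.20 (0.0342), and the matrix genes Col14a1 by 1.04 ± 0.18 (0.03) and Fmod by 1.10. Interferon-inducible genes rose, with Ifi27 (ENSMUSG00000064215, chromosome 12, 103434211 to 103440239) at 1.91 ± 0.12 (edgeR adjusted p = 9.65e-05), from 12.4 to 38.2 CPM at E13 and from 12.6 to 57.6 CPM at E15. Bst2 (ENSMUSG00000046718, chromosome 8, 71534255 to 71537456) rose by 2.20 ± 0.31 (edgeR adjusted p = 0.0139), Ifitm3 by 1.07 ± 0.16 (0.0162) and the MHC light chain gene B2m by 0.62 (0.0267). Ifitm3 thus rose in fibroblast-like cells and fell in epithelial-like cells.

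**Figure D4:**
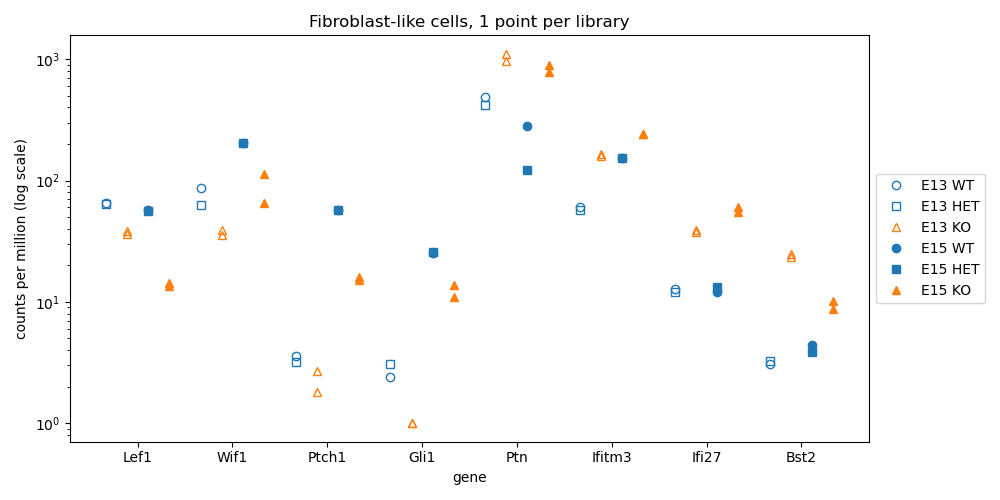
CPM on a log scale (vertical axis) of 8 genes in fibroblast-like cells, with 1 point per library, blue for control and orange for KO, open for E13 and filled for E15, and values under 1 drawn at 1. Lef1, Wif1, Ptch1 and Gli1 were lower and Ptn, Ifitm3, Ifi27 and Bst2 higher in KO than in control at both ages.

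Epithelial genes also differed in fibroblast-like cells, with the same direction as in epithelial-like cells. Krt14 was at -7.72 ± 0.30 (edgeR adjusted p = 2.21e-06), Krt5 at -5.53 (0.000218), Krt18 at 5.94 (0.000195), Krt8 at 4.85 (0.00178), Cldn3 at 2.996 and Trp63 at -3.67 (0.0471). The list of basal keratinocyte genes had 4 falls among 12 (camera adjusted p = 2.38e-31, adjusted p = 0.00682 with an estimated correlation), and simple epithelium genes had 3 rises among 10 (camera adjusted p = 2.07e-14, adjusted p = 0.042 with an estimated correlation). The p63 target list had 3 falls among 16 (camera adjusted p = 7.22e-06, adjusted p = 0.145 with an estimated correlation). Desmosome and junction genes had 2 falls (camera adjusted p = 0.000335, adjusted p = 0.268 with an estimated correlation), basement membrane genes 1 fall (0.00201, adjusted p = 0.171 with an estimated correlation), hair placode genes 2 falls (0.00309, adjusted p = 0.216 with an estimated correlation), epithelial markers 1 rise (0.0145, adjusted p = 0.528 with an estimated correlation) and differentiation genes, with a median of -0.90 and the test pointing to falls, 1 rise (0.042, adjusted p = 0.345 with an estimated correlation).

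Of the other lists in fibroblast-like cells, the interferon response passed with either correlation, with 4 rises among 10 genes and a median of 1.46 (camera adjusted p = 4.67e-17, adjusted p = 0.0276 with an estimated correlation). The Wnt response list had 2 falls among 12, and adjusted over the list alone 8 falls and 1 rise (camera adjusted p = 2.01e-08, adjusted p = 0.0734 with an estimated correlation). The upper dermis list had 2 falls among 11 (camera adjusted p = 5.05e-08, adjusted p = 0.0734 with an estimated correlation), and the Hedgehog response list had 2 falls among 6 (camera adjusted p = 3.92e-07, adjusted p = 0.106 with an estimated correlation). The lower dermis and fat list had no called gene, but adjusted over the list alone 9 of 11 rose (camera adjusted p = 2.79e-07, adjusted p = 0.216 with an estimated correlation). FGF and ERK response (camera adjusted p = 2.79e-07, adjusted p = 0.229 with an estimated correlation) and G2 and M phase genes (1.13e-08, adjusted p = 0.302 with an estimated correlation) were lower, and fibrillar matrix genes had 2 rises among 20 (9.62e-05, adjusted p = 0.411 with an estimated correlation). S phase (camera adjusted p = 0.00682), anterior Hox (0.0145), macrophage (0.018), muscle (6.9e-05) and MHC class I genes (0.029) were also called, and their adjusted p was 0.528, 0.411, 0.505, 0.327 and 0.268 with an estimated correlation.

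The lists that camera did not call in fibroblast-like cells were endothelial (adjusted p = 0.0556), p53 response (0.0651), dissociation stress (0.0917), dermal condensate (0.109), periderm (0.256), mesenchymal (0.372), BMP and TGF-beta (0.442), neuron (0.583), cartilage (0.617), posterior Hox (0.617), bone and cartilage (0.617), Notch (0.724), hypoxia and glycolysis (0.797) and erythroid (0.801). Bone and cartilage genes had 5 tested members, none called. The dermal condensate result leaves out unnamed cluster 27, whose leading genes included the condensate genes Bmp4 and Bmp3. That cluster had 33 and 39 cells in the E15 WT and HET libraries and 0 in KO. The periderm median of 0.67 and the direction of its test differed in sign, as did the Notch median of 0.06 and the hypoxia median of 0.01. The KO effect differed between ages in 291 genes of fibroblast-like cells by edgeR, 184 higher and 107 lower at E15. The lower cell quality of the E15 control libraries was not separated from this. Lef1 differed by -1.29 ± 0.14 (edgeR adjusted p = 0.00964), the Wnt inhibitor gene Dkk1 by -3.16 (0.00954), Ptch1 by -1.29 (0.0447), the BMP response genes Id1, Id2 and Id3 by -1.87, -1.32 and -1.24, the FGF response gene Dusp6 by -1.38 and the elastin gene Eln by 1.58. The count of 291 was 1276 without the gene filter, and 23, 30, 118, 67, 70, 138 and 63 without E13 WT, E13 HET, E13 KO 1, E13 KO 2, E15 HET, E15 KO 1 or E15 KO 2.

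From E13 to E15, control fibroblast-like cells had 2151 rises and 1967 falls (edgeR, n = 2 against 2). Barcodes over the mitochondrial limit numbered 3 and 7 in the E13 control libraries and 54 and 68 at E15, a difference in quality that was not separated from age. Fibrillar matrix genes had 16 rises among 20 (camera adjusted p = 2.02e-18, adjusted p = 0.281 with an estimated correlation), with Col1a1 at 2.40 (edgeR adjusted p = 1.36e-05), Col3a1 at 2.02 and Col1a2 at 1.83. Hedgehog response genes had 5 rises among 6 (camera adjusted p = 4.96e-10, adjusted p = 0.225 with an estimated correlation), with Ptch1 at 4.27 and Gli1 at 3.39, and the fat regulators Pparg and Cebpa rose by 3.87 and 2.87. Cldn10 rose by 7.71 (edgeR adjusted p = 7.63e-07) and Clec3b by 7.32, whereas the neuronal tubulin gene Tubb3 changed by -5.97, Ntm by -5.36 and Sfrp1 by -2.90. The calbindin gene Calb1 had 1 UMI at E15 and an E13 to E15 ratio of 1.54e+03 (Poisson interval 277 to 6.09e+04). The count of 4118 was 2319, 2564, 2681 and 2704 without E13 WT, E13 HET, E15 WT or E15 HET.

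KO fibroblast-like cells had 2632 rises and 2211 falls from E13 to E15 (edgeR, n = 2 against 2), a count of 4843 that was 3135 without E13 KO 1. Fibrillar matrix genes had 18 rises among 20 (camera adjusted p = 2.77e-29, adjusted p = 0.176 with an estimated correlation), with the proteoglycan gene Dcn at 2.67 and Col6a1 at 2.30. Ly6a rose by 8.47, Clec3b by 8.07 and Sfrp5 by 6.67. The mast cell marker Tpsb2 had 1 UMI in E13 KO and an E15 to E13 ratio of 1.13e+03 (Poisson interval 203 to 4.48e+04), and whether this was RNA of mast-like cells was not tested. Wnt response genes had 7 falls and 1 rise (camera adjusted p = 4.32e-05, adjusted p = 0.176 with an estimated correlation), with Lef1 at -1.29 and Dkk1 at -2.53, and BMP and TGF-beta response genes had 8 falls and 1 rise among 12 (camera adjusted p = 0.00138, adjusted p = 0.18 with an estimated correlation), with Id3 at -1.96. In HET against WT fibroblast-like cells no gene passed in edgeR (370 had unadjusted p below 0.05), DESeq2 called 5, and 41 passed in edgeR without the gene filter. The count of 0 was 8 and 2 without E13 HET or E15 HET. Camera called 11 lists there and none with an estimated correlation.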

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

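The tests on the keratin pattern of epithelial-like cells and on other splits of the libraries were chosen after those results were seen. Each value that follows is a difference of the KO effect between ages, at E15 minus at E13 on the log2 scale. The lower cell quality of the E15 control libraries was not separated from these differences. For genes this difference passed in the interaction term of edgeR. For lists camera with the preset correlation found the members' differences to stand apart from those of the other genes, which does not show that a median differs from 0. None of the lists passed with an estimated correlation.

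In epithelial-like cells Krt15 differed by 4.48 and Krt10 by -4.73. Among the lists with a positive median difference were p63 targets at 0.53 (0.81 with members at 0 set to their bound), simple epithelium at 0.68 and periderm at 1.95, as well as macrophage markers at 2.06 and erythroid markers at 1.78. The negative medians of epithelial and signalling lists were -0.27 for basement membrane and hemidesmosome (-0.527 with its member at 0 set to its bound), -1.34 for hair placode (-1.16 with bounds), -1.54 for the Wnt response (-1.92 with bounds), -1.97 for the Hedgehog response and -0.55 for the FGF and ERK response. Tissue lists had medians of -1.31 for mesenchymal genes, -0.26 for fibrillar matrix, -2.05 for dermal condensate, -2.97 for bone and cartilage and -2.44 for posterior Hox genes. State lists had medians of -0.26 for S phase, -0.49 for G2 and M phase, -1.53 for hypoxia and glycolysis and -1.01 for dissociation stress. Fibroblast markers were at -0.88 and neuron markers at -4.30 (-3.97 with bounds). In the comparison over both ages the dermal condensate and neuron lists had few tested genes, and bone and cartilage too few to test. The neuron markers Tubb3 and Nefm had 0 UMIs in E15 KO, so the medians of such lists rest on few, low-level genes.

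In fibroblast-like cells Krt1 differed by -4.42, Krt10 by -1.69, Ifitm3 by -0.89 and Lef1 by -1.29. List medians were -3.06 for differentiation (-3.02 with bounds), -0.39 for the Wnt response, -0.83 for the BMP and TGF-beta response, -1.19 for the FGF and ERK response, -0.13 for upper dermis, -0.22 for G2 and M phase, -1.04 for the interferon response and -0.24 for hypoxia and glycolysis. Fibrillar matrix was at 0.52 and dissociation stress at 0.45. Epithelial markers were at -1.15, endothelial markers at -1.29 and erythroid markers at 1.24. Free RNA of epithelial cells was not tested for the differences of Krt1, Krt10, the differentiation list and the epithelial markers. Epithelial-like cluster 29, led by Krt1, Krt10 and Lor, had 26 and 7 cells in the E15 WT and HET libraries and 0 in KO. These values therefore cannot be read as changes in fibroblast-like cells themselves.

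Krt8 and Krt18 were higher and Krt5 and Krt14 lower in KO epithelial-like cells. Free RNA in the droplets was tested by the summed Krt8 and Krt18 level in epithelial-like over fibroblast-like cells, whose lowest ratio over the KO libraries was 18.2, which argues against it. A minority of cells of another simple epithelium was tested by the share of KO cells with a UMI of either gene after thinning to 4000 UMIs, whose lowest value was 85.7%, which also argues against it. The test bears on a minority alone and not on a simple epithelium that makes up most of the KO class. In control, 17 of 177 cells of E13 WT, 5 of 160 of E13 HET, 1 of 53 of E15 WT and 0 of 25 of E15 HET had such a UMI. Periderm cells making up the KO class may still contribute, since the periderm list was at -0.6985 at E13 and 1.4593 at E15. The direct effect of p63 loss on this epithelium remains a hypothesis beside it and was not tested apart from it.

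Of 15 epithelial response genes that differed in KO fibroblast-like cells, 11, among them Krt14, Krt5, Krt8 and Krt18, were at least 10 times higher in epithelial-like cells and were tested here, a choice that favours free RNA. Col7a1, Fgfr2, Klf4 and Lef1 were not and were left out. Free RNA of epithelial cells could explain the 11, since the median log2 ratio of their level in other classes over fibroblast-like cells was 0.537, so that the other classes carried as much of them. Kremen2 was an exception, at 14.75 CPM in other classes of control and 13.78 CPM in those of KO. Doublets of a fibroblast and an epithelial cell were tested by the share of these UMIs in the top 5% of fibroblast-like cells over the share expected from depth, whose median was 1.02, which argues against them, although the E15 KO libraries were at 1.48 and 1.17.

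Lef1, Wif1, Tcf4, Gli1 and Ptch1 were lower in KO fibroblast-like cells. Another mix of fibroblast-like clusters may account for part of this, since the within-cluster effect was 0.362 of that of the whole class, with Lef1 lower in KO in 15 of 15 clusters and the other genes in 11 to 13. The clusters were drawn without Lef1 but with the other genes open to use, so the test does not settle it. Libraries taken at another level of the trunk were tested by leaving out those with over 10 CPM of Hoxa10. The effects without them were 1.004 times those with all libraries by the median over these genes, while the tests no longer passed (edgeR adjusted p from 0.113 to 0.195 with 2 residual degrees of freedom). This does not settle that explanation, since the E15 libraries left still differed in Hoxa10, at 8.001 CPM in E15 KO 2 and 1.89 in E15 WT. A lower signal from the p63-deficient epithelium remains open and was not tested.

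Other splits of the 8 libraries into 4 and 4 were fitted to the same model, 34 of the 35 that exist, since the split by age could not be fitted. In epithelial-like cells 1 of 34 splits, the real one, called as many as 2383 genes, and the highest other split called 0. In fibroblast-like cells 1 of 34 splits, again the real one, called as many as 118 genes, and the highest other split called 4. Only 18 of these splits keep 2 libraries of each age on both sides as the real one does, too few for a share under 0.05. The other splits also keep any KO effect in their residual, which lowers their counts, so the gap to the real split is no measure of the size of the effect.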

How the results depend on the processing

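The tests on left-out libraries were planned, and 4 alternatives were chosen after the data were seen: the first naming rule, unnamed clusters added, libraries with fewer than 30 epithelial-like cells left out, and libraries high in Hoxa10 left out. Over the alternatives run, 12118 single results (of the genes, shares and lists reported here) stayed on their side of the threshold, while 1222 no longer passed, 247 newly passed and 17 moved in value or count. Of the comparison-level results 128 stayed within 1.5 times and 60 moved. No class share passed under any alternative run, and where 11 classes were adjusted together a single class could not. The per-cell gate gave 50, 33, 3 and 2 epithelial-like cells in E13 WT, E13 HET, E15 WT and E15 HET. It gave 68, 70, 14 and 29 in E13 KO 1, E13 KO 2, E15 KO 1 and E15 KO 2, so the direction of the epithelial share was reversed. The 6 detection shares that passed were 6 after thinning to 4000 UMIs and 7 without thinning. The 1 added was Krt1, which without thinning was also in 16.99 to 60.66% of fibroblast-like cells per control library and 1.49 to 11.48% per KO library. Scaling alternatives moved the median of all genes by at most 0.045. In epithelial-like cells the KO against control count of 2383 was 246 with each cell thinned to 2000 UMIs, where 2453 genes were tested, 915 with thinned libraries, and 1147 against HET alone with fewer libraries. The interaction count of 355 was 1029 without the gene filter, and HET against WT went from 0 to 15 without the filter and 3 in DESeq2. In fibroblast-like cells the count of 118 was 1093 without the filter, 409 in DESeq2, 75 with 2 times the doublets removed, 232 and 233 at Leiden resolutions 0.5 and 2, 53 with response genes kept, 245 with the per-cell gate, 36 against WT and 74 against HET alone, 623 as the average of the 2 age effects, 537 with the first naming rule (E15 only) and 18 without the libraries high in Hoxa10 (5 libraries). The cause was not tested except where fewer genes or libraries are named. The fibroblast interaction count of 291 was 1276 without the filter, and HET against WT went from 0 to 41 without it and 5 in DESeq2. The 10 lists called in epithelial-like cells were 0 with an estimated correlation. With libraries left out in turn, where a lone library was assumed to vary like the other groups, the epithelial counts ranged from 1448 to 3015 for KO against control, 1045 to 3606 at E13, 808 to 1628 at E15, 76 to 513 for the interaction, 946 to 1720 for age in control, 913 to 3331 for age in KO and 0 to 2 for HET against WT. The fibroblast counts ranged from 51 to 134, 23 to 202 for the interaction, 2319 to 4060 and 3135 to 4921 for age in control and KO, and 0 to 8 for HET against WT.

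A replicate block pairing the KO libraries by number called 3335 genes for age in epithelial-like cells and 4044 in fibroblast-like cells with 1 residual degree of freedom. The correlation of deviations over the 2 pairs was -0.0361 and -0.0788, which gives no sign that the numbers pair the samples, though 2 pairs cannot exclude it. KO against control in other classes was not run. The 16 and 26 epithelial-like cells of E15 KO 1 and E15 HET limit what low-level genes can show at E15.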

Other observations

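No tests in this part were chosen after the result was seen. Epithelial-like KO cells also differed from control in lists not described for single ages so far. At E13 the Notch pathway had 5 falls and 1 rise among 7 genes (camera adjusted p = 1.14e-06, adjusted p = 0.131 with an estimated correlation), and BMP and TGF-beta response genes had 3 rises among 11 (camera adjusted p = 0.00778, adjusted p = 0.198 with an estimated correlation). Hair placode genes had 5 falls among 12 at E13 (camera adjusted p = 0.0029, adjusted p = 0.171 with an estimated correlation), differentiation genes 4 falls among 17 (camera adjusted p = 0.00882, adjusted p = 0.56 with an estimated correlation) and p53 response genes 5 falls and 1 rise (camera adjusted p = 0.0497, adjusted p = 0.465 with an estimated correlation). At E15 the Notch pathway had 5 falls among 7 genes (camera adjusted p = 1.97e-06, adjusted p = 0.223 with an estimated correlation), with a median of -3.07, or -1.86 with members at 0 set to their bound. FGF and ERK response genes had 4 falls among 7 at E15 (camera adjusted p = 0.00171, adjusted p = 0.385 with an estimated correlation), and p63 target genes 7 falls and 2 rises among 20 (camera adjusted p = 0.00193, adjusted p = 0.223 with an estimated correlation).

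The posterior gene Hoxa10 stood at 1.46, 0.282, 0.598, 28.5, 1.89, 20.6, 50.7 and 8.001 CPM in fibroblast-like cells of E13 WT, E13 HET, E13 KO 1, E13 KO 2, E15 WT, E15 HET, E15 KO 1 and E15 KO 2. Its neighbour in body position Hoxc10 stood at 24.9, 8.38, 12.2, 58.9, 20.8, 80.8, 134 and 45.3 CPM. Xist, the transcript of the inactive X chromosome, was at 1316, 1141, 1421 and 1537 CPM in the E13 libraries. Barcodes over the mitochondrial limit numbered 3, 7, 7 and 10 in the E13 libraries and 54, 68, 6 and 8 in the E15 libraries. The share of barcodes kept was 96.6, 96.7, 97.1 and 96.7% at E13 and 79.5, 70.7, 86.9 and 87.4% at E15.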
